A study of Homo sapiens with 24 samples.

How the data were processed

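RNA from the human multiple myeloma cell line ARP1 was sequenced after 24 h of culture with LPA or with PBS, the vehicle. LPA is taken here as lysophosphatidic acid, a lipid that signals through G protein-coupled receptors; the labels give only the abbreviation, and write its dose as 4 mg/mL, which is high for this lipid in culture, so the unit is in doubt. Total RNA was extracted on Qiagen columns and made into libraries for DNB (DNA nanoball) sequencing, per the labels. The titles name 6 libraries, PBS 1 to 3 and LPA 1 to 3, each read in 4 lanes, which makes 24 samples. Groups were taken from the treatment label and library and lane numbers from the titles, and the 4 lanes of a library were counted as 1 replicate, so n = 3 per group. Nothing in the labels says that the libraries of a group came from separate cultures.

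The authors deposited 1 table of FPM, the CPM unit for fragments (counts scaled to the total of the lane), with 1 column for each of the 24 lanes. No column of values was left unmapped. The aligner, the counting tool, its strand setting and its rule for reads that match several genes are not given in the sources used here. The submitters' processing notes name the mouse build mm10, whereas all 19158 gene identifiers in the table are human Ensembl identifiers, so no coordinates are given. In every lane the values are whole multiples of the value of 1 read, and that step gives a whole number of reads as the total by which the authors divided. Within a tolerance of 0.02 reads, 100% of the values came out as whole reads. The genes listed in the table sum to between 86.5% and 91.6% of these totals per library, so part of what was counted is not in the table. The lowest total of any listed gene was 10 reads over the 24 lanes. Genes with fewer reads are not listed in the table.

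The table held 19345 rows with a gene and 1 blank line, which was left out. Some gene symbols had been turned into dates, as spreadsheets do, so genes were matched by identifier. Of the rows, 187 repeated an identifier with the same values and were dropped, leaving 19158 genes. Symbols came from a table of Ensembl gene names, in which 19118 identifiers were found; biotypes, GC content and transcript length came from GENCODE release 29, in which 19065 were found. For 66 identifiers the reads were identical to those of another identifier in every lane. With the counting rule not known, values of near-identical copies are uncertain. That holds for histones, HLA genes, ribosomal proteins, snoRNAs, 7SL RNA, the Alu-derived BCYRN1, CCL3 and CCL4, and GYPB. It also holds for genes that overlap another gene or a read-through transcript, among the named genes RSAD2 and CMPK2, IFIT1 to IFIT3 with LIPA, NME1, HSPE1, ABHD14A, BSCL2, and LPAR6 within RB1.

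Recovered reads were summed over lanes. Library totals were 5615625, 5529582 and 5498910 reads for PBS 1 to 3 and 8740992, 7446950 and 6941747 for LPA 1 to 3. At these totals 1 read is worth between 0.114 and 0.182 FPM, and 3 reads, the limit that a count of 0 allows, between 0.343 and 0.546 FPM. Reads are not counted as separate molecules, so such limits cover counting error only.

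The mean FPM over the 4 lanes was taken for each library. Genes with at least 1 FPM in at least 3 of the 6 libraries were tested (16274), on log2(FPM + 1), with limma-trend and robust empirical Bayes, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes on this scale understate the change of low genes. The values per library, and the group means and SDs given with them, are on the FPM scale. Because the median gene shifted between the groups, counts are given also on FPM rescaled by median-of-ratios size factors. Two-sided exact permutation tests were used for single values, for which 3 libraries against 3 allow no p below 0.1.

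Before the data were examined, 39 gene lists with 888 entries, the test, the alternatives and the rule for naming genes were written down. A list was tested if at least 5 of its members were tested, which held for 34 lists. The test was limma's camera with a preset correlation between genes of 0.01, which sets the members against all other genes, with Benjamini-Hochberg adjustment over the 34 lists; camera with an estimated correlation and fry were alternatives. Fry tests the members against no change rather than against other genes. On deposited FPM it thus takes in the shift of the median gene. For each list the members past the threshold were counted, adjusted over all genes and adjusted over the list alone. Genes were named by rule. Among genes past the threshold with at least 5 FPM in the higher group and with the 3 LPA libraries all above or all below the 3 PBS libraries, the 12 highest and the 12 lowest by log2 fold change were taken. Besides these, up to 4 members of each list with the smallest p were taken, the members with the highest mean where none passed, and the LPA receptors. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

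The alternatives were another pseudocount, filter, scaling or threshold, limma with 1 prior variance, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, single lanes, the replicate number as a block, and each library left out in turn. On recovered reads edgeR called 3263 genes and DESeq2 1710. Software versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

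The steps were tested on simulated counts with the real gene means and library totals, a dispersion of 0.01 and 50 changed genes at each size. In this simulated comparison of LPA with PBS, limma was run on 16291 genes. It recovered 2, 29, 47 and 50 of the 50 genes at absolute log2 fold changes of 0.3, 0.5, 1 and 2, none with the wrong sign, with 10 false calls among 16091 unchanged genes. On the same counts edgeR made 6 false calls among 14897 unchanged genes and DESeq2 2 among 18958. Of the 34 lists, the 1 that had been shifted was called and 0 others were. Genes were drawn independently of each other, so false list calls from members that vary together were not tested.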

Results

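ARP1 is a human multiple myeloma cell line, a cancer of antibody-secreting plasma cells. The series asked which genes change when ARP1 cells are cultured for 24 h with LPA rather than with PBS. RNA was measured in 3 libraries per treatment, each sequenced in 4 lanes that were counted as 1 replicate. The libraries held between 5498910 and 5615625 reads in the PBS group and between 6941747 and 8740992 in the LPA group. Values are in FPM (CPM), reads scaled to the library total, given as mean ± SD over n = 3 libraries, and log2 fold changes are of LPA over PBS on the log2(FPM + 1) scale. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. PBS 1 and PBS 3 differed by little more than lanes of 1 library did, with a chi-square per degree of freedom of 1.34 against 1.15 to 1.19 between lanes, and so did LPA 1 and LPA 2, with 1.35. PBS 2 stood apart from the other PBS libraries, with 3.69 and 3.78, and LPA 3 from the other LPA libraries, with 2.42 and 2.83. Between a PBS and an LPA library the ratio ranged from 7.35 to 12.8. A lane holds fewer reads than a library and the ratio can rise with reads, so lane and library ratios compare only roughly.

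With LPA, most of the listed interferon response, NF-kappaB target and immediate early genes fell. Most of the listed histone, MYC target, DNA replication and cell division genes rose. The largest change was in IFIT2 (ENSG00000119922), an interferon-induced RNA-binding protein, which fell from 129 ± 2.17 to 8.34 ± 0.592 FPM, 15.5-fold lower. Large falls outnumbered large rises: of the genes past the threshold, 89 were at least 2-fold lower and 14 at least 2-fold higher. These counts were 117 and 5 on rescaled FPM, 185 and 22 by edgeR and 164 and 12 by DESeq2. Of the 89 genes lower by limma on FPM, 38 were small nucleolar RNAs. Of the 6 LPA receptor genes, the 3 that were listed were low in both groups and none of these passed the test.

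By limma, 4397 of 16274 tested genes (27.0%) differed between LPA and PBS at an adjusted p below 0.05, of which 3666 were higher with LPA and 731 lower. This split rested on the scaling. The median gene was higher with LPA by 0.13 on the log2 scale, and on rescaled FPM, where the median was 0.01, 3130 genes passed, 1633 higher and 1497 lower. On recovered reads edgeR called 1673 higher and 1590 lower, and DESeq2 818 higher and 892 lower. All 1633 genes higher on rescaled FPM were among the 3666, and 720 of the 731 lower genes were lower on both scales. Between limma on FPM and each of these other fits, 0 genes were called in opposite directions. Each of the other fits centres the median gene, which moves most fold changes down, so such overlap is largely built in. The 3 LPA libraries lay all above or all below the 3 PBS libraries for 6322 genes (38.8%), with 5115 above and 1207 below. On rescaled FPM this held for 5474 genes (33.6%), with 2782 above and 2692 below. Chance gives 10% of the tested genes on average. Genes are not independent, so a single grouping of the libraries can lie far from that share. List medians are given relative to the median of all genes, while the log2 fold changes of single genes include the shift of 0.13.

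**Figure D1:**
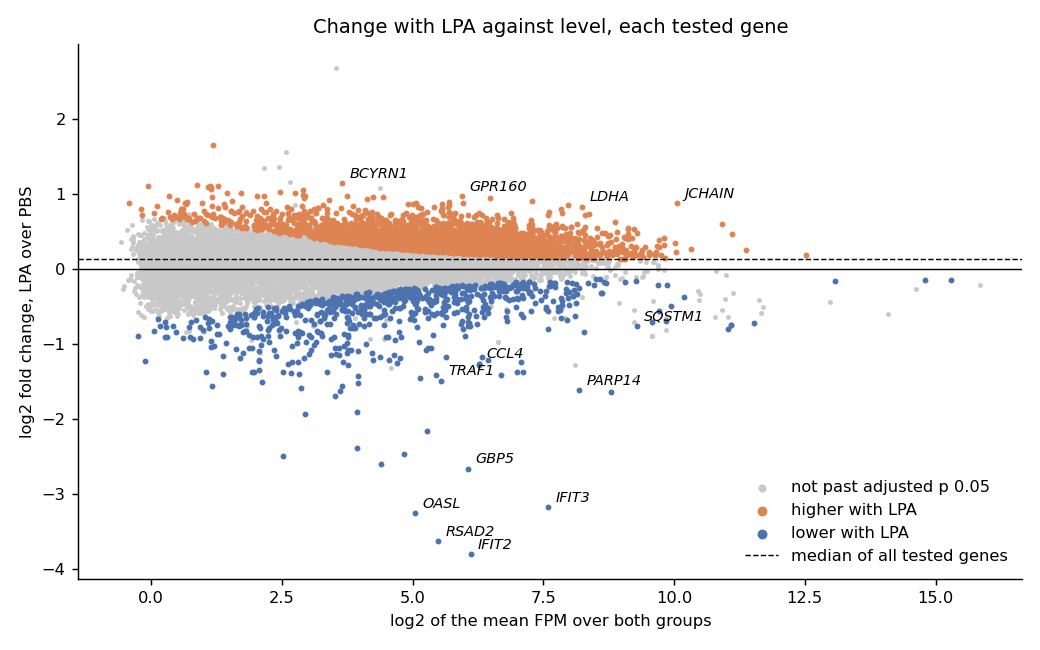
Log2 fold change of LPA over PBS (vertical axis) against the log2 of the mean FPM over both groups (horizontal axis) for the 16274 tested genes, 1 point per gene, with genes past the limma threshold in colour. The median gene lies at 0.13, and the largest changes are falls, down to -3.80 for IFIT2.

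The classes of RNA that make up the reads moved with the treatment. Nuclear protein-coding genes took 58.6% ± 2.02 of the reads in the PBS libraries and 65.4% ± 2.07 in the LPA libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). The share of 7SL RNA, the RNA of the signal recognition particle, was 10.7% ± 0.871 with PBS and 9.35% ± 0.244 with LPA, and that of 7SK RNA 2.75% ± 0.175 and 2.30% ± 0.264. Small nucleolar, small nuclear and Cajal body RNAs together took 2.29% ± 0.506 and 1.36% ± 0.0544. The nuclear RNAs MALAT1 and NEAT1 took 3.35% ± 0.140 and 2.92% ± 0.0544, and the ribosomal DNA-associated MIR663AHG and MIR3648 2.85% ± 0.414 and 1.86% ± 0.169. Transcripts of the mitochondrial genome took 3.21% ± 0.501 and 2.30% ± 0.233. Each of these shares had non-overlapping groups and the same exact p of 0.1. As parts of 1 total, a rise in 1 share lowers others, so these are not independent results. Reads counted by the authors outside the listed genes were 12.6% ± 0.931 and 10.7% ± 2.07 (exact p = 0.2). PBS 2 stood out here as well, with 60.9% protein-coding, 3.79% mitochondrial and 1.72% small nucleolar, nuclear and Cajal body RNA.

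**Figure D2:**
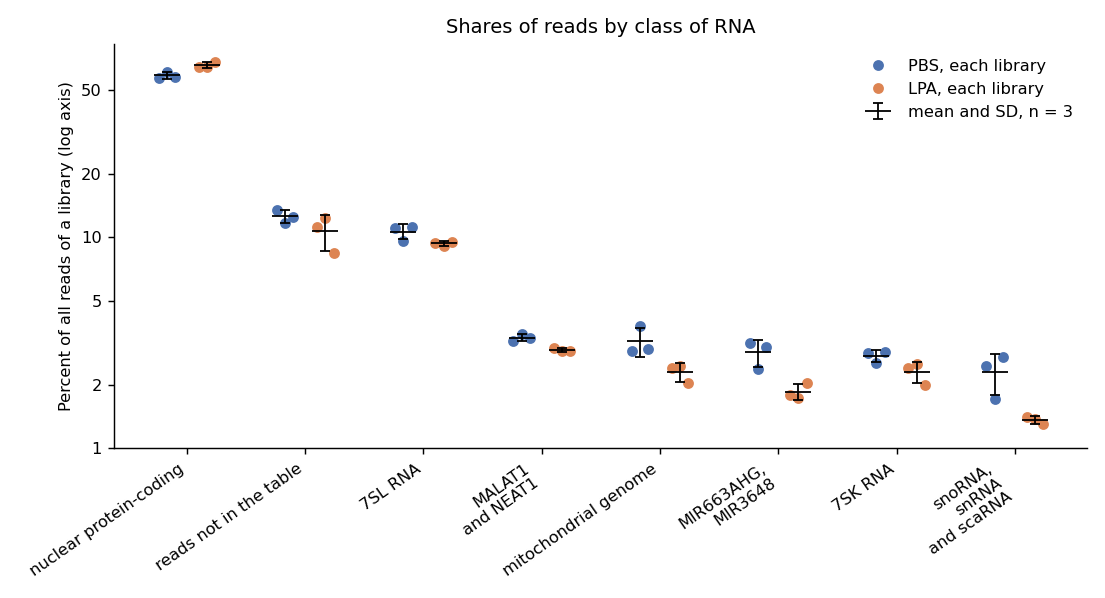
Share of each library's reads, in percent on a log axis, by class of RNA, with 1 point per library and the group mean ± SD (n = 3). Nuclear protein-coding genes took 58.6% of reads with PBS and 65.4% with LPA, and the small nucleolar, nuclear and Cajal body RNAs 2.29% and 1.36%.

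Of the 12 genes that fell most, 7 are in the interferon response list. After IFIT2 came RSAD2 (ENSG00000134321), the antiviral enzyme viperin, which fell from 84.1 ± 0.686 to 5.94 ± 1.07 FPM, and OASL, an antiviral 2'-5'-oligoadenylate synthetase-like protein, from 60.9 ± 3.68 to 5.5 ± 0.781 FPM. IFIT3 (ENSG00000119917), which binds IFIT1 and IFIT2, fell from 347 ± 14.8 to 37.7 ± 3.47 FPM, a log2 fold change of -3.17 (SE 0.07, limma adjusted p = 1.54e-38). The guanylate-binding protein GBP5 fell from 115 to 17.4 FPM and the chemokine CCL5 from 36.7 to 5.25 FPM. DDX60, IFIT1, IFI44, CMPK2 and the ubiquitin-like ISG15 had log2 fold changes of -2.46, -2.38, -2.16, -1.94 and -1.90. XIRP1, an actin-binding protein, fell from 10.4 to 1.14 FPM, with a log2 fold change of -2.49 that was -1.50 with a pseudocount of 4 FPM. In the whole list of interferon response genes, 26 of 30 tested members fell, 26 adjusted over the list alone, 0 rose and 4 did not pass. The list median was -0.79 relative to all genes (limma camera, adjusted p = 2.56e-52). On rescaled FPM 27 fell, and the call held with an estimated correlation (adjusted p = 0.00866). Without PBS 2, 1 member passed as higher.

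Inflammatory and immediate early genes were lower as groups. Of 16 tested NF-kappaB target genes 14 fell, 15 adjusted over the list alone, and 0 rose, with a median of -0.76 relative to all genes (camera adjusted p = 3.12e-23, and adjusted p = 0.00866 with an estimated correlation). Among them TRAF1, an adaptor of TNF receptors, fell from 68.8 ± 1.98 to 23.9 ± 1.09 FPM, the NF-kappaB inhibitor TNFAIP3 from 122 ± 4.45 to 51.7 ± 2.5 FPM, and the chemokines CCL4 and CCL3 from 109.9 to 45.1 FPM and from 1005 to 680.0 FPM. Of 19 immediate early genes 12 fell, 13 adjusted over the list alone and 13 on rescaled FPM, and 2 rose, with a median of -0.64 (camera adjusted p = 4.95e-13, and adjusted p = 0.0184 with an estimated correlation). FOS and JUNB, subunits of the transcription factor AP-1, fell from 43.1 to 24.7 FPM and from 132 to 89.6 FPM, and IER5 and KLF6 from 52 to 24.1 FPM and from 298 to 213 FPM. The members that rose, named after their values were seen, were KLF2 at 0.30 and BTG2 at 0.21 on the log2 scale. On rescaled FPM neither passed. Nor did KLF2 pass at 0.26 without PBS 1, PBS 3 or LPA 2, or BTG2 at 0.15 without PBS 1, 0.17 without PBS 3, 0.21 without LPA 1 and 0.18 without LPA 3, and 0 members were higher without PBS 1 or PBS 3 and 1 without LPA 1, LPA 2 or LPA 3. Of 19 genes of MHC class I and II antigen presentation 9 were lower (10 adjusted over the list alone and 11 on rescaled FPM), 9 did not pass and 1 was higher, HLA-DPA1, named after its value was seen, which was not past the threshold on rescaled FPM or at 0.24 without PBS 3. HLA-E fell from 261 to 176 FPM, the peptide transporter TAP1 from 267 to 182 FPM and HLA-F from 30.3 to 15.7 FPM. This list's camera adjusted p was 3.09e-07, and it did not hold with an estimated correlation (adjusted p = 0.0828). The count of higher members was 3 without PBS 2 and 0 without PBS 3.

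Histone and MYC target genes rose as groups. Of 22 replication-dependent histone genes 21 rose, 21 adjusted over the list alone and 19 on rescaled FPM, with a median of 0.51 relative to all genes (camera adjusted p = 4.19e-16, and adjusted p = 0.00866 with an estimated correlation). H3C2 rose from 119 ± 4.1 to 188 ± 5.4 FPM, H1-4 from 177 ± 11.3 to 259 ± 9.11 FPM, H1-3 from 30.6 to 54.7 FPM and H2BC7 from 41.8 to 70.4 FPM. Of 25 MYC target genes 22 rose, 22 adjusted over the list alone and 14 on rescaled FPM, with a median of 0.27 (camera adjusted p = 4.39e-10, and adjusted p = 0.0168 with an estimated correlation). Lactate dehydrogenase LDHA rose from 217 ± 11.8 to 387 ± 4.23 FPM, the nucleoside diphosphate kinase NME1 from 36.8 to 65.9 FPM, the nucleolar protein NOLC1 from 125 to 187 FPM and ornithine decarboxylase ODC1 from 89.8 to 137 FPM. The gene MYC itself, looked up after the list was seen, rose from 7.07 ± 1.74 to 14.1 ± 0.706 FPM (log2 fold change 0.92, limma adjusted p = 7.30e-06).

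Genes of the cell cycle were higher with LPA as well. Of 31 genes of DNA replication and the G1/S transition 25 rose, 30 adjusted over the list alone and 19 on rescaled FPM, with a median of 0.28 relative to all genes (camera adjusted p = 5.82e-13; adjusted p = 0.08 with an estimated correlation). Among them the ribonucleotide reductase subunit RRM2 rose from 170.1 to 259 FPM, the replicative helicase subunit MCM2 from 123 to 183 FPM and thymidylate synthase TYMS from 99.2 to 144 FPM. Of 30 genes of G2/M and cell division 25 rose, with a median of 0.28 (camera adjusted p = 1.83e-10; adjusted p = 0.078 with an estimated correlation). Adjusted over the list alone, 28 were higher and 1 lower, and on rescaled FPM 20 and 1. Without PBS 2, 1 was lower over all genes. The proliferation marker MKI67 rose from 239 to 337 FPM, topoisomerase TOP2A from 237 to 315 FPM, the spindle checkpoint kinase BUB1B from 62.2 to 92.4 FPM and the mitotic motor KIF11 from 74 to 106 FPM.

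**Figure D3:**
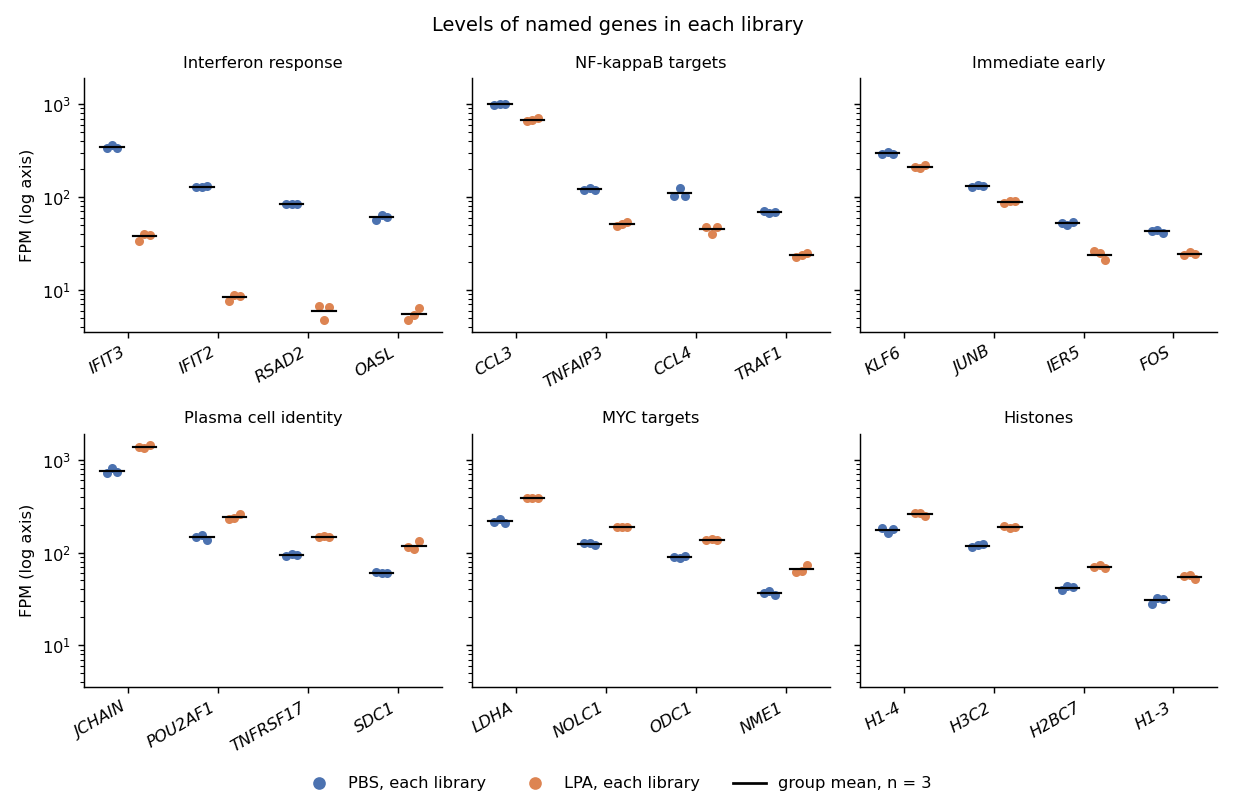
Level in FPM (log axis) of 24 named genes of 6 lists in each library, 1 point per library, with the group mean (n = 3). All 3 LPA libraries lie below all 3 PBS libraries in the interferon, NF-kappaB and immediate early panels, and above them in the plasma cell, MYC target and histone panels. The genes shown are the 4 of each list with the smallest p in this comparison, so the lack of overlap is largely built in.

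The lists of plasma cell identity and of the unfolded protein response had medians above that of all genes, and neither call held with an estimated correlation. Of 23 genes of plasma cell and myeloma identity 14 rose and 9 did not pass, with a median of 0.31 relative to all genes (camera adjusted p = 2.84e-06; adjusted p = 0.219 with an estimated correlation). Adjusted over the list alone 16 were higher and 1 lower, and on rescaled FPM 11 and 2. Without PBS 1, 1 was lower over all genes. JCHAIN, the joining chain of polymeric immunoglobulin, rose from 754 ± 48.9 to 1379 ± 48.6 FPM, the plasma cell surface proteoglycan SDC1 (CD138) from 60.7 ± 1.2 to 118 ± 11.9 FPM, the B cell coactivator POU2AF1 from 145 to 240.1 FPM and the receptor TNFRSF17 (BCMA) from 94.4 to 148 FPM. Of 24 genes of the unfolded protein response 15 rose, 15 adjusted over the list alone and 13 on rescaled FPM, with a median of 0.16 (camera adjusted p = 1.64e-06; adjusted p = 0.078 with an estimated correlation). The members with the smallest p were folding proteins of the endoplasmic reticulum: HSP90B1 rose from 453 to 655 FPM, CANX from 477 to 631 FPM, PDIA6 from 312 to 420.0 FPM and PDIA4 from 125 to 177 FPM.

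Of 76 cytosolic ribosomal protein genes 50 were higher, 60 adjusted over the list alone but 15 on rescaled FPM, with a median of 0.06 relative to all genes (camera adjusted p = 9.81e-09; adjusted p = 0.0631 with an estimated correlation). Without PBS 2 the median was 0.02, and with edgeR's values the list was not called (adjusted p = 0.0696). RPL4 and RPLP0 rose from 915 to 1166 FPM and from 1154 to 1392 FPM, and RPL5 from 336 to 427 FPM. Of 55 nuclear genes of the respiratory chain 33 were higher, 40 adjusted over the list alone and 12 on rescaled FPM, with a median of 0.13 (camera adjusted p = 9.88e-07; adjusted p = 0.078 with an estimated correlation). The ATP synthase subunits ATP5F1B and ATP5PB rose from 234 to 305 FPM and from 50.1 to 72.5 FPM, and NDUFS1 of complex I and COX8A of complex IV from 119 to 155 FPM and from 34.6 to 50.7 FPM. The list of the 13 protein genes of the mitochondrial genome had a median of -0.58 relative to all genes. It was called lower with a preset correlation (camera adjusted p = 1.29e-16) and not with an estimated one (adjusted p = 0.154). Only ND2 passed, from 2648 ± 379 to 1525 ± 268 FPM (limma adjusted p = 0.0439), and 0 members adjusted over the list alone, against 3 lower on rescaled FPM. The ND2 call was lost without any 1 of the libraries, with log2 fold changes of -0.86, -0.69 and -0.86 without PBS 1, 2 and 3 and -0.86, -0.90 and -0.65 without LPA 1, 2 and 3. The count of lower members was 3 without PBS 2 or LPA 3 and 0 without LPA 1 or LPA 2. With the replicate number as a block it was 13, although the values gave no sign that replicate numbers pair the libraries. Without both PBS 2 and LPA 3, a setting chosen after the values were seen, the list median was -0.35 and ND2 was at -0.53. The 4 libraries then left differ within a group by little more than lanes do, so no p is given.

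Glycolysis and both lipid synthesis lists were called higher with a preset correlation and not with an estimated one. None of these calls held with a filter at 5 FPM, upper-quartile scaling, 1 prior variance or edgeR (adjusted p between 0.0696 and 0.261). Of 23 glycolysis genes 13 were higher and 3 lower, 14 and 3 adjusted over the list alone and 9 and 5 on rescaled FPM, with a median of 0.11 relative to all genes (camera adjusted p = 0.0235; adjusted p = 0.589 with an estimated correlation). Besides LDHA, PGK1 rose from 491 to 712 FPM, ENO1 from 506 to 673 FPM and PGAM1 from 131 to 179 FPM. The lower members, named after their values were seen, were PFKL, ENO2 and SLC16A3. Their calls were lost for PFKL at -0.15 without LPA 2, for ENO2 at -0.27 without PBS 3 and -0.24 without LPA 2, and for SLC16A3 at -0.38 without PBS 1, -0.36 without PBS 2 or LPA 1 and -0.35 without LPA 2. The glycolysis call did not hold on rescaled FPM (adjusted p = 0.0611) or without LPA 3 (median 0.10, adjusted p = 0.0572), and 0 members were lower without LPA 2. Cholesterol synthesis had 12 of 24 members higher and 0 lower, 13 and 0 adjusted over the list alone and 5 and 2 on rescaled FPM, with a median of 0.05 (camera adjusted p = 0.0214; adjusted p = 0.589 with an estimated correlation, and 0.211 on rescaled FPM). MSMO1, SQLE and CYP51A1, enzymes of this pathway, rose with log2 fold changes of 0.38, 0.44 and 0.30. The median was 0.03 without PBS 1 (adjusted p = 0.0619), 0.09 without PBS 3 and 0.03 without LPA 1, and 7 members were higher without PBS 1 or without LPA 3. Fatty acid and lipid synthesis had 8 of 16 members higher and 1 lower, 9 and 1 adjusted over the list alone and 4 and 2 on rescaled FPM, with a median of 0.09 (camera adjusted p = 0.0384; adjusted p = 0.589 with an estimated correlation, and 0.151 on rescaled FPM). FASN, SCD, ACLY and FADS1, enzymes of fatty acid synthesis and desaturation, rose with log2 fold changes of 0.51, 0.38, 0.42 and 0.40, and SREBF1, a transcription factor of lipid synthesis, fell by 0.39. That list was not called without PBS 1 (median 0.03, adjusted p = 0.0683), PBS 3 (0.11, adjusted p = 0.0557) or LPA 3 (0.09, adjusted p = 0.0572). Nor was it called with the replicate number as a block (camera adjusted p = 0.0506). It had 4 higher members without LPA 1, and SREBF1 did not pass without PBS 1 (-0.31) or LPA 1 (-0.30).

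The antioxidant, hypoxia and ATF4 response lists had medians below that of all genes, and their calls did not hold with an estimated correlation. Of 22 antioxidant and NRF2 target genes 2 rose and 2 fell, 2 and 2 adjusted over the list alone, against 1 and 13 on rescaled FPM, with a median of -0.22 (camera adjusted p = 8.11e-04; adjusted p = 0.291 with an estimated correlation). The autophagy receptor SQSTM1 fell from 786 ± 27.7 to 465 ± 27.4 FPM and the ferritin heavy chain FTH1 from 314 to 249.7 FPM, while TALDO1 and PGD of the pentose phosphate pathway rose from 29.9 to 40.7 FPM and from 93.8 to 109 FPM. PGD did not pass on rescaled FPM, nor without PBS 1, PBS 3, LPA 1 or LPA 3, where its log2 fold changes were 0.21, 0.18, 0.23 and 0.18. Of 19 hypoxia genes 1 rose and 5 fell, 3 and 5 adjusted over the list alone and 1 and 7 on rescaled FPM, with a median of -0.15 (camera adjusted p = 0.0208; adjusted p = 0.291 with an estimated correlation). ERO1A rose from 55.8 to 77.5 FPM, and DDIT4, NDRG1 and ADM fell from 44.8 to 30.8 FPM, from 208 to 162 FPM and from 6.79 to 3.78 FPM. EGLN3 and PDK1, named after their values were seen, also fell. EGLN3 did not pass at -0.65 without PBS 1 and was 0.29 in lane 2 alone, and PDK1 did not pass at -0.19 without PBS 3 and -0.18 without LPA 1, or with the replicate number as a block (adjusted p = 0.0520). Higher members numbered 5 without PBS 2 and 2 without LPA 3. Of 23 genes of the ATF4 amino acid response 3 rose and 6 fell, 6 and 7 adjusted over the list alone and 0 and 9 on rescaled FPM, with a median of -0.11 (camera adjusted p = 0.0225; adjusted p = 0.589 with an estimated correlation). The phosphatase subunit PPP1R15A (GADD34) fell from 82.7 to 50.2 FPM and the transcription factor DDIT3 (CHOP) from 27.4 to 19.9 FPM, while the amino acid transporters SLC7A5 and SLC7A1 and, named after its value was seen, PSAT1 were higher by 0.24, 0.26 and 0.23, and did not pass on rescaled FPM. Lower members of the ATF4 list numbered 3 without PBS 1, LPA 1 or LPA 2, and higher ones 6 without PBS 2 and 1 without PBS 3, where SLC7A1 (0.21) did not pass. PSAT1 did not pass at 0.20 without PBS 1, 0.21 without PBS 3 and 0.18 without LPA 1 or LPA 3.

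**Figure D4:**
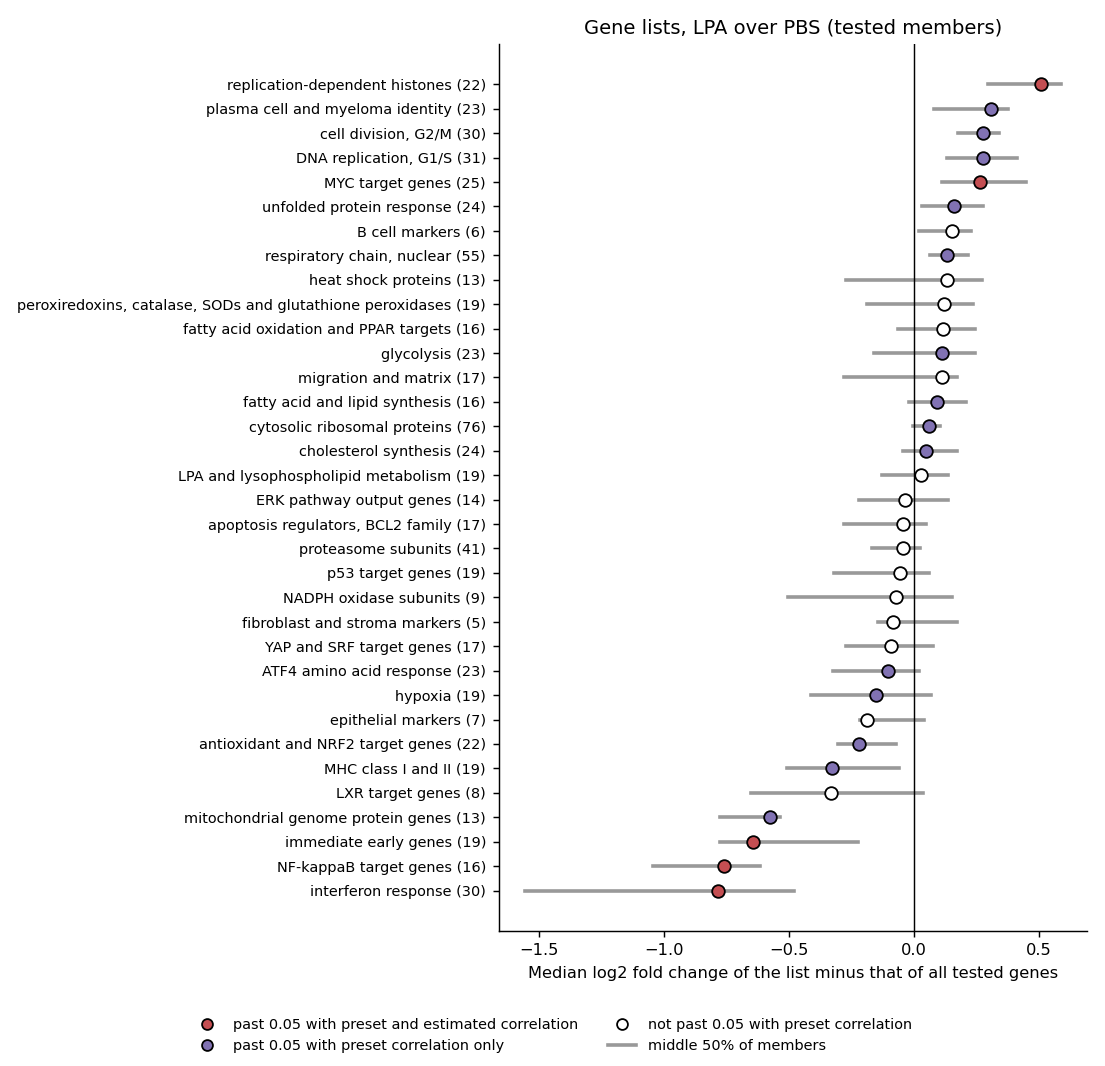
Median log2 fold change of each tested list minus that of all genes (horizontal axis), with a bar for the middle 50% of its members, the number of tested members in brackets, and colours for the camera call at 0.05 with a preset and an estimated correlation. The medians run from -0.79 for the interferon response to 0.51 for replication-dependent histones.

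Of the 6 LPA receptor genes 3 were in the table, in which every gene has at least 10 reads over the 24 lanes. LPAR1, LPAR4 and LPAR5 were not. Part of the counted reads lay outside the listed genes, so their absence does not show that they were low. LPAR2 was at 3.97 ± 0.677 FPM with PBS and 3.53 ± 0.589 with LPA (limma adjusted p = 0.684), and LPAR3 at 1.14 ± 0.278 and 0.999 ± 0.0794 (adjusted p = 0.835). LPAR6 was at 3.97 ± 0.326 and 5.75 ± 0.932 FPM, a log2 fold change of 0.43 (adjusted p = 0.086). Its gene lies within RB1. By limma 0 receptors passed, over all genes or adjusted over the list alone, and 1 had an unadjusted p below 0.05. On rescaled FPM, with edgeR (2 tested) and with DESeq2 the counts were 0 and 0. Of 19 genes of LPA and lysophospholipid metabolism 5 were higher and 0 lower, 5 and 0 adjusted over the list alone and 2 and 2 on rescaled FPM, and the list did not stand apart (median 0.03, mean 0.00, camera adjusted p = 0.525). The lysophospholipase LYPLA1 rose from 64.4 to 90.7 FPM and the acyltransferase GPAM from 19.9 to 30.4 FPM. The other 3 were AGPAT3, LIPH and, named after its value was seen, LPCAT1, none of which passed on rescaled FPM. AGPAT3 did not pass without LPA 3 (0.19), and LIPH without PBS 1 (0.38), PBS 3 (0.29) or LPA 3 (0.33). LPCAT1 did not pass at 0.24 without PBS 3 and 0.19 without LPA 3. The count of higher members was 9 without PBS 2, 3 without PBS 3 and 2 without LPA 3.

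Lists of signalling output and migration did not stand apart from all genes by camera. By fry the migration list was called higher (adjusted p = 0.0378). On rescaled FPM its fry direction was lower, with an unadjusted fry p of 0.485. Among 14 ERK output genes 3 rose and 2 fell, the same adjusted over the list alone and 2 and 3 on rescaled FPM (median -0.03, camera adjusted p = 0.639). Cyclin D1 (CCND1) and SPRED2 rose from 451 to 607 FPM and from 41.8 to 55.8 FPM, PHLDA1 and IER3 fell from 6.39 to 2.95 FPM and from 6.32 to 3.11 FPM, although IER3 was 0.054 in lane 4 alone. SPRED1, named after its value was seen, was higher by 0.29 and did not pass on rescaled FPM or at 0.25 without PBS 3. Among 17 YAP and SRF target genes 3 rose and 4 fell, 4 and 4 adjusted over the list alone and 1 and 4 on rescaled FPM (median -0.09, camera adjusted p = 0.188). ACTB was higher, from 738 to 842 FPM, but did not pass on rescaled FPM (log2 fold change 0.047, adjusted p = 0.634) or by edgeR or DESeq2. FLNA fell from 1007 to 867 FPM, while AJUBA and PTPN14 did not pass without LPA 3 (0.63 and -0.40). WWC1 rose and ACTG1 and TPM1 fell, named after their values were seen. WWC1 did not pass on rescaled FPM or at 0.35 without PBS 1, 0.26 without PBS 3 or LPA 3 and 0.34 without LPA 1, and was -0.17 in lane 4 alone. ACTG1 did not pass at -0.13 without PBS 1 or LPA 2, -0.12 without PBS 2 or LPA 1 and -0.17 without PBS 3, nor TPM1 at -0.50 without PBS 1, -0.59 without PBS 2 and -0.58 without LPA 1 or LPA 3. With the replicate number as a block WWC1 (adjusted p = 0.0529) and ACTG1 (0.134) did not pass. Without LPA 3, 1 YAP and SRF target was higher, and without PBS 1, PBS 2, LPA 1 or LPA 3, 2 were lower. Among 17 genes of migration and matrix 7 rose and 3 fell, the same adjusted over the list alone and 4 and 4 on rescaled FPM (median 0.11, mean -0.03, camera adjusted p = 0.956). The chemokine receptor CXCR4 rose from 82.9 to 132 FPM, the adhesion receptor CD44 from 443 to 547 FPM and RHOA from 216 to 263 FPM, and RHOB fell from 57.2 to 37.6 FPM, as did PLAU and VIM, named after their values were seen. PLAU did not pass at -0.46 without PBS 2 and -0.54 without LPA 3, nor VIM at -0.15 without PBS 1 or LPA 2 and -0.13 without LPA 1 or with the replicate number as a block (adjusted p = 0.0660).

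Apoptosis and oxidant lists were not called by camera on deposited FPM either. Among 17 regulators of the BCL2 family 3 rose and 4 fell, 4 and 5 adjusted over the list alone and 1 and 5 on rescaled FPM (median -0.04, camera adjusted p = 0.188). The list was called lower with upper-quartile scaling, scaling to protein-coding reads and the GC and length correction (adjusted p = 0.0494, 0.0484 and 0.0451). BCL2 fell from 268 to 223 FPM, BBC3 (PUMA) from 12.2 to 7.44 FPM and BIRC3 from 213 to 181 FPM, as did HRK, and BIK, BCL2L1 and BMF were higher. Of these BIK did not pass without LPA 3 (0.52), and HRK, BCL2L1 and BMF were named after their values were seen. BCL2L1 and BMF did not pass on rescaled FPM, BCL2L1 did not pass at 0.28 without PBS 3, 0.31 without LPA 1 and 0.21 without LPA 2, and HRK did not at -0.50 without PBS 1, -0.49 without PBS 2, -0.55 without PBS 3, -0.43 without LPA 1 and -0.39 without LPA 2, and was 0.30 in lane 2 alone. Among 19 p53 target genes 4 rose and 3 fell, the same adjusted over the list alone and 1 and 4 on rescaled FPM (median -0.06, camera adjusted p = 0.197). FAS fell from 32.9 to 23.2 FPM and AEN rose from 23.8 to 32.4 FPM, while ZMAT3 at 0.49 did not pass on rescaled FPM. GDF15, lower, and MDM2 and POLH, higher, were named after their values were seen. MDM2 and POLH did not pass on rescaled FPM, MDM2 did not pass at 0.16 without PBS 1, 0.20 without PBS 3 or LPA 1 and 0.19 without LPA 3, and GDF15 did not at -0.66 without PBS 1 or LPA 2, -0.51 without PBS 3, -0.64 without LPA 1 and -0.73 without LPA 3, and was 0.15 in lane 3 alone. Among 19 peroxiredoxins, catalase, superoxide dismutases and glutathione peroxidases 7 rose and 2 fell, the same adjusted over the list alone and 4 and 3 on rescaled FPM (median 0.12, camera adjusted p = 0.529). By fry this list was called higher (adjusted p = 0.0138), with an unadjusted fry p of 0.333 on rescaled FPM. PRDX4 of the endoplasmic reticulum rose from 60.2 to 99.4 FPM, PRDX3 from 53.7 to 70.5 FPM and PRDX2 from 45.9 to 60 FPM. GPX3 fell from 26.8 to 17.4 FPM, as did SOD2, named after its value was seen, which did not pass at -0.19 without PBS 3 and -0.17 without LPA 1, leaving 1 lower member. Among 9 NADPH oxidase subunits 4 rose and 1 fell, the same adjusted over the list alone and 1 and 2 on rescaled FPM (median -0.07, camera adjusted p = 0.601). CYBA rose from 48.4 to 67.6 FPM. RAC1, RAC2 and, named after its value was seen, CYBB did not pass on rescaled FPM, RAC2 did not pass without PBS 3 (0.21) or CYBB at 0.71 without PBS 1 and 0.65 without PBS 2 or PBS 3, and 2 members were higher without PBS 3 and 2 lower without PBS 2.

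Among 41 proteasome subunits 7 rose and 3 fell, the same adjusted over the list alone and 2 and 12 on rescaled FPM. The list was not called (median -0.04, camera adjusted p = 0.642) but was called lower on rescaled FPM (adjusted p = 0.0189) and with upper-quartile scaling, scaling to protein-coding reads and the GC and length correction (0.0105, 0.00938 and 0.00309). The interferon-inducible subunit PSMB9 fell from 54.1 to 43 FPM, as did PSMB10 and PSME2, named after their values were seen, and PSMD8 and PSME3 rose from 45.7 to 64.3 FPM and from 78.6 to 101 FPM. PSMB10 did not pass at -0.24 without PBS 1, -0.29 without LPA 1 and -0.28 without LPA 2, and PSME2 did not at -0.23 without LPA 2 and was 0.033 in lane 3 alone. Without LPA 2, 1 subunit was lower. Among 13 heat shock proteins 8 rose and 2 fell, 8 and 3 adjusted over the list alone and 6 and 4 on rescaled FPM (median 0.13, camera adjusted p = 0.105). The list was called higher in lanes 2, 3 and 4 alone (camera adjusted p = 0.0226, 0.00719 and 0.0292). It was also called higher by fry (adjusted p = 0.00199), with an unadjusted fry p of 0.0452 on rescaled FPM. HSPA8 rose from 370.3 to 570.3 FPM, HSP90AB1 from 773 to 1029 FPM, HSP90AA1 from 796 to 995 FPM and HSPE1 from 31.4 to 47.1 FPM. HSPA1B and HSPB1, named after their values were seen, fell. HSPB1 did not pass at -0.29 without PBS 1, -0.26 without PBS 3, -0.31 without LPA 1 and -0.30 without LPA 3, which left 1 lower member. Among 16 genes of fatty acid oxidation and PPAR targets 7 rose and 0 fell, 9 and 1 adjusted over the list alone and 3 and 2 on rescaled FPM (median 0.12, camera adjusted p = 0.129). By fry the list was called higher (adjusted p = 0.0166), with an unadjusted fry p of 0.0306 on rescaled FPM. CPT1A rose from 72 to 103 FPM, ACADM from 35.8 to 49.9 FPM and the fatty acid-binding protein FABP5 from 6.37 to 11.9 FPM. Without LPA 3, 4 members were higher, and without PBS 1, 1 was lower. Among 8 LXR target genes 1 rose and 2 fell, 2 and 4 adjusted over the list alone and 1 and 4 on rescaled FPM (median -0.33, camera adjusted p = 0.052). The cholesterol exporter ABCG1 fell from 3.91 ± 0.285 to 1.5 ± 0.452 FPM. Without PBS 2 (-0.35, adjusted p = 0.0429) or LPA 2 (-0.40, adjusted p = 0.0338) the LXR list was called. It was also called with no filter (adjusted p = 0.0473), 1 prior variance (0.0407), lane 3 alone (0.00909) and thinned reads (0.0437). Its other changed members, SREBF1 and NR1H3, did not pass without LPA 1 (-0.30 and 0.49) nor SREBF1 without PBS 1 (-0.31), and 4 members were lower without LPA 2 and 1 without PBS 1 or LPA 1.

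Markers of other cell types were few and low. Of 6 B cell markers BLK was higher (from 12.7 to 16.7 FPM), and the call was lost on rescaled FPM and without PBS 1 (0.37), PBS 2 (0.31), LPA 1 (0.34) or LPA 2 (0.36). The list had a camera adjusted p of 0.831, but was called higher by fry (adjusted p = 0.0453, and unadjusted p = 0.108 on rescaled FPM). Of 5 fibroblast and stroma markers FN1 was higher (from 24.5 to 35.2 FPM), which did not pass on rescaled FPM, and COL1A1 was lower (from 14.6 to 10.2 FPM), which did not pass without PBS 3 (-0.35) or LPA 3 (-0.41). The list had a camera adjusted p of 0.639. Of 7 epithelial markers 0 passed by limma (camera adjusted p = 0.396), with ESRP1 at 28.6 and 32.5 FPM and ELF3 at 14.2 and 12.6 FPM. Too few members were tested for camera in the remaining lists. Of 2 myeloid markers FCER1G fell from 9.14 to 4.62 FPM, of 3 T and NK cell markers 0 passed, with KLRD1 at 22.6 and 25.1 FPM and CD8A at 4.09 and 5.38, and of 2 metallothionein-list genes 0 passed, MTF1 at 47.8 and 51.4 FPM and SLC30A1 at 22.9 and 21.9. The erythroid marker GYPB was higher (from 3.31 to 5.47 FPM) but did not pass on rescaled FPM, nor without PBS 1 (0.42), LPA 1 (0.61) or LPA 3 (0.49). The counts in these lists were the same adjusted over the list alone.

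The largest rises of single genes were smaller than the largest falls. The 12 highest by the rule had log2 fold changes between 0.95 and 1.14. They were led by BCYRN1, a non-coding RNA of Alu origin whose reads other Alu copies share, from 7.46 ± 0.577 to 17.7 ± 1.12 FPM, and the calcium-binding copine CPNE5, from 4.56 ± 1.12 to 10.4 ± 0.737 FPM. HPGD, which degrades prostaglandins, rose from 3.31 to 7.7 FPM, with a log2 fold change of 1.03 that was 0.68 with a pseudocount of 4 FPM, and the protease inhibitor SLPI from 2.46 to 5.67 FPM, with 0.97 and 0.59. The orphan receptor GPR160 (ENSG00000173890) rose from 41.2 ± 3.89 to 81.5 ± 3.6 FPM (limma adjusted p = 2.52e-13) and the interleukin 13 receptor chain IL13RA1 from 14.3 ± 1.14 to 28.8 ± 2.6 FPM. METAP1D, MLC1, PTP4A3, ARHGAP9 and BSCL2 had log2 fold changes of 1.01, 0.99, 0.98, 0.97 and 0.95. ABHD14A was at 9.05 ± 3.87 FPM with PBS and 17.7 ± 1.31 with LPA (adjusted p = 0.0412), and its call was lost on rescaled FPM (adjusted p = 0.109) and without PBS 2, LPA 2 or LPA 3 (log2 fold changes of 1.02, 0.98 and 0.92).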

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

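The settings with protein-coding scaling, thinned reads, the GC and length correction, and without both PBS 2 and LPA 3 were chosen after seeing the data. Against 4397 genes changed, 3666 higher and 731 lower, settings that centre the median gene moved the split and less so the total. Median-of-ratios scaling gave 3130 changed (1633 higher, 1497 lower), upper-quartile scaling 3045 (1440, 1605), edgeR on recovered reads 3263 (1673, 1590), scaling to nuclear protein-coding reads 3053 (1425, 1628) and the GC and length correction of rescaled values 3134 (1820, 1314). These settings bring the median gene from 0.13 to between -0.01 and 0.02, and a lower median moves calls from higher to lower by construction. EdgeR also changes the test and the GC and length correction also removes a trend, and these parts were not separated. DESeq2 called 1710 genes (818 higher, 892 lower) and limma with 1 prior variance 2039 (1566, 473); the cause was not tested. Lanes 1 to 4 alone, with fewer reads per library, gave 1559, 1608, 1515 and 1506 genes, of which 1269, 1310, 1226 and 1239 were higher and 290, 298, 289 and 267 lower. An adjusted p below 0.01 left 2814 genes (2337, 477), and an absolute log2 fold change of at least 1 left 103 (14, 89), as stricter thresholds do. Leaving out 1 library at a time gave between 3177 and 5189 genes changed, 2463 to 4487 higher, 543 to 714 lower, and 17 to 20 lists. Reads thinned to the same total gave 4076 genes. Calls without both PBS 2 and LPA 3 rest on libraries that differ within a group by little more than lanes do, so their number is not given. Of the 19 lists called with a preset correlation, 5 were called with an estimated one (interferon response, NF-kappaB targets, immediate early genes, MYC targets and histones), which allows for members that vary together; the other settings called 15 to 21 lists. No setting called a listed LPA receptor past the threshold.

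Changed settings gave 4723 comparisons of 198 genes, taken by the naming rule or chosen later. In 4083 the gene stayed on the same side of the threshold, with the same direction where it passed. Where a gene passed in neither fit, direction was not compared, and MTF1, for one, was at 0.11 and on rescaled FPM at -0.034. In 634 comparisons the gene kept direction and no longer passed. In 6 a gene past the threshold changed direction, each in 1 lane alone. IER3 (-0.82 over all lanes) was 0.054 in lane 4 alone, EGLN3 (-0.78) 0.29 in lane 2 alone, WWC1 (0.34) -0.17 in lane 4 alone, HRK (-0.51) 0.30 in lane 2 alone, GDF15 (-0.67) 0.15 in lane 3 alone and PSME2 (-0.31) 0.033 in lane 3 alone; the cause was not tested. Of the 188 of these genes past the threshold, 92 did not pass in at least 1 lane alone, 30 on rescaled FPM, 27 with edgeR, 42 with DESeq2 and 56 with 1 prior variance. Leaving out 1 library ended the call of 42 of them and turned no sign: 22, 9 and 24 without PBS 1, 2 and 3, and 22, 14 and 21 without LPA 1, 2 and 3. Of 879 comparisons of 34 lists, 800 left a called list called or an uncalled list uncalled, 57 lost the call and 22 gained it. As to depth, 1 read is worth up to 0.182 FPM. In the simulated comparison limma recovered 2 of 50 genes at an absolute log2 fold change of 0.3 and 29 of 50 at 0.5. Recovery by level was not tested. The simulation gave all libraries the same dispersion, which the real libraries do not share. In the data ACTB passed at 0.19 (limma adjusted p = 0.00109), so the simulated rates may not carry over.

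The values gave no sign that replicate numbers pair the libraries. Deviations from the group means of same-numbered libraries correlated, across genes, at -0.01, -0.04 and -0.05, and no library correlated best with its own number. Since some libraries of a group differ by little more than lanes do, such correlations could miss a pairing. With the replicate number as a block, 4059 genes changed (3339 higher, 720 lower) and 18 lists were called, without fatty acid and lipid synthesis (adjusted p = 0.0506). Under the block PDK1, WWC1, ACTG1, VIM and MALAT1 no longer passed (adjusted p = 0.0520, 0.0529, 0.134, 0.0660 and 0.0748), 13 instead of 1 of the protein genes of the mitochondrial genome were lower, and 4 instead of 7 genes of fatty acid oxidation were higher.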

Other observations

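The settings named here as thinned, corrected for GC content or scaled to protein-coding reads were chosen after seeing the data, and the tests of a few abundant RNAs and of markers of other cell types after the result itself was seen. The genes in the first paragraphs were also chosen after their values were seen.

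Small nucleolar RNAs, which guide the chemical modification of ribosomal and other RNAs, were lower with LPA. Of 119 tested 71 fell and 0 rose by limma (72 and 0 on rescaled FPM), with a median of -0.88 relative to all genes. Those named SNORA, which guide pseudouridylation, fell in 60 of 88, with a median of -1.04, and those named SNORD, which mostly guide methylation, in 10 of 28, with a median of -0.68. The most abundant that passed were SNORA63, from 678 ± 169.7 to 212 ± 15.5 FPM, SNORA53, from 284 ± 33.7 to 216 ± 11.4 FPM, and SNORA23, from 187 ± 17.9 to 136 ± 2.77 FPM. SNORA53 did not pass on rescaled FPM (log2 fold change -0.53, adjusted p = 0.082). PBS 2 had the lowest share of small nucleolar, nuclear and Cajal body RNA among the PBS libraries, 1.72%. The share was 2.44% in PBS 1, 2.70% in PBS 3 and 1.41% in LPA 1, the highest of the LPA libraries. Whether the fall came from the treatment or from handling of the RNA was not tested. The long nuclear RNA NEAT1 fell from 3646 to 2228 FPM, and MALAT1 from 29847 to 27014 FPM, which did not pass with the replicate number as a block (adjusted p = 0.0748).

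Of the 89 genes at least 2-fold lower, 38 were small nucleolar RNAs, 18 were in a fixed list (13 of them in the interferon response list) and 33 were in neither. Among these 33 the ADP-ribosyltransferase PARP14 fell from 439 ± 24.9 to 142 ± 4.5 FPM, the antiviral zinc finger protein ZC3HAV1 from 190.4 to 80 FPM, the transcription factor IRF1 from 112 to 49 FPM and DHX58, a relative of the RNA sensors, from 19 to 5.91 FPM. The secreted chitinase-like CHI3L1 fell from 69.3 to 30.3 FPM. The RNA sensors IFIH1 (MDA5) and DDX58 (RIG-I), both in the interferon list, fell from 151 to 55.8 FPM and from 26.8 to 11.1 FPM. The DNA sensor CGAS was at 43.7 and 45.2 FPM (limma adjusted p = 0.743), and STING1 at 23 and 31 FPM (adjusted p = 0.00378, and 0.0547 on rescaled FPM), which did not pass at 0.27 without LPA 3. The myeloma survival factor IRF4 rose from 343 ± 11.9 to 477 ± 22.5 FPM and the plasma cell transcription factor XBP1 from 201 to 273 FPM.

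The fall of the interferon list, -0.79 relative to all genes, was weighed against technical explanations. A shift caused by a few abundant RNAs moves all genes alike, and so does not account for a list that lies at -0.79 relative to all genes. With reads thinned to 1 total the list was still at -0.79 relative to all genes. Since thinning leaves each gene's expected FPM as it was, that covers only the counting noise of unequal depth. Cells of another type that carry an interferon response in the PBS cultures cannot be told apart: 2 of 23 tested markers of 5 other cell types fell (FCER1G and COL1A1), but as few as 2 markers were tested for a type, and the most abundant, ESRP1 and FN1, stood at 28.6 and 24.5 FPM with PBS. A lower interferon signal in the LPA cultures may come from the treatment, or from a difference in handling between the groups, for which the labels give no batch. Neither was tested.

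The median gene was 0.13 higher with LPA. With reads thinned to the same total it was still 0.13. Thinning leaves each gene's expected FPM as it was, so this covers only the counting noise of unequal depth, and read depth was not decided. A smaller share of a few abundant non-coding and mitochondrial RNAs in the LPA libraries (7SL RNA 10.7% against 9.35% of reads) may underlie the shift, but this was not decided. Scaled to reads on nuclear protein-coding genes the median was -0.0083, but 13859 of the 16274 tested genes are protein-coding, so this scaling centres the median by construction.

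The large number of small to moderate changes was weighed against sequence and copy number. With a trend in GC content and length removed from rescaled values 3134 genes passed, against 3130 without that step, although fold changes correlated with GC content across genes (Spearman's rho -0.19, genes not being independent). A change in chromosome copy number would move whole chromosomes, and the largest distance of a chromosome's median from that of all genes was 0.056. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 4397 genes and the highest other 0, and the real one 19 lists and the highest other 12. The real split was the only 1 to reach each, and 10 splits are too few for a share under 0.05. Every other split puts PBS and LPA libraries into the same group, so the difference between treatments adds to the spread within groups. Low gene counts there are largely built in, and the splits do not show what chance gives. The changes may come from the treatment or from anything else that differed between the groups, such as culture density or the day of extraction, which the labels do not give.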
